A study of Mus musculus with 15 samples.

How the data were processed

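Comparative genomic hybridisation arrays of 15 mouse mammary carcinomas were analysed, each with tumour DNA labelled with Cy3 and liver DNA labelled with Cy5, per the labels. The dyes were never swapped. Tumours were grouped by the tumour grade in the labels (3, 4, 5 and 3 tumours of Grades 1 to 4), and replicate numbers within a grade were given in the order of the records and pair nothing. The slide of each array was taken from the labels.

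The values used were log2 ratios as deposited by the authors in their processed value table, with 42076 probes for each of 15 arrays and 2 decimals. Per the submitters' processing notes, limma 2.12.10 and the mm9 genome build were used. The background correction, the kind of normalization and any probe filters are not given in the sources used here, and the direction of the ratio is not recorded. The scale was taken as log2, since limma gives log2 ratios. The medians of the deposited columns lay between -0.02 and 0.01, so the arrays had been centred or normalized. The scanner intensities were not used here. A red over green ratio with these dyes would be liver over tumour. The values instead held ratios of up to 119 in one direction only, and an amplification of that size can only lie in tumour DNA, so positive was taken as likely tumour over liver. This reads the high values as amplification. A loss of both copies in tumour DNA, seen through a ratio of liver over tumour, was not tested. Each array was centred on its median again, and no further normalization was applied. A missing dye swap leaves each probe's own dye bias in the ratio. All 105 pairs of arrays correlated positively (r from 0.0311 to 0.827, median 0.456; 0.527 within slides and 0.424 between slides). No 2 arrays were identical.

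The table gives probe numbers, and the gene table used here (of assembly GRCm38) lists none of them, so 0 probes were matched to a gene or position. The segments, chromosome means and gene lists that had been fixed before the data were examined therefore could not be computed. The fixed fallback to single probes was used for the altered share (probes at least 1 from 0), for the 2 limma comparisons and for high-level changes. A high-level threshold of 1, fixed beforehand, is within the noise of single probes. A threshold of 2 in at least 3 probes was chosen after seeing the data. A probe belonged to the shared amplified set when it was at 2 or above in at least 2 tumours, and to the core when it was so in each of the 9 tumours that shared probes. By the rule for named items, probe numbers were given for the smallest p in each direction, limited to 2 that rose and 2 that fell.

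In place of chromosomes, groups of probes that shift together were sought after seeing the data. A mixture of Gaussian distributions over the 15 tumours with 1 shared covariance and 30 components was fitted to the 41911 probes without a value of 2 or above (scikit-learn 1.9.0, best of 8 random starts). A probe was a member of a component at a probability over 0.9. A component of at least 50 probes was kept as a group when components with a Jaccard index of at least 0.7 to it were found in at least 3 of 4 other fits, with 22, 26, 34 and 38 components. The Bayesian information criterion still fell at 38 components, so 30 was a choice and not an optimum. The level of a group in a tumour is the mean of its members, and a level at least 0.25 from 0 was called a gain or a loss. Members set from the other 14 tumours gave a level within 0.05 for 198 of 208 values, and 34 of the 39 called levels that could be set this way kept their call. The mixture was not fitted again for this, so the tumour left out still shaped the groups and the check is not independent. Without Grade 4 replicate 2, group 5 had 22 members, against 1337, and its level was not set. The groups are not known to be whole chromosomes, and the remaining probes belong to no group. For the altered share all 30 components were also used, each counted by its weight and called by its fitted mean. Since the array median is the zero point, a level in a tumour with many changes is relative to that median. On simulated arrays with 20 chromosomes that changed only as a whole, 9 stable groups were found. The least pure had 98.0% of its probes from 1 chromosome, so in that setting the method left out chromosomes but mixed few. The largest error of a group's level was 0.152, and the median over groups of the largest error was 0.0999, against the 0.25 used for calls. Small changes and changes of parts of chromosomes were not simulated.

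Group levels were tested against 0 with the exact two-sided sign-flip permutation test and against grade with Spearman's rho and Pearson's r (two-sided permutation test, 100000 resamples), with Benjamini-Hochberg adjustment over 14 groups. Presence of the amplified set was tested against grade over all arrangements of the tumours. Single probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with grade as a number, and as Grade 4 minus Grade 1 in a fit of 4 grade means. In simulated data of 41911 probes with the residual correlation of the real arrays, the grade trend recovered 14 of 50 probes with a slope of 0.2 per grade, 37 of 50 with 0.3 and 47 of 50 with 0.4, with 0 false calls. Grade 4 minus Grade 1 recovered 5, 29 and 45 of 50 of these, with 0 false calls. The residuals came from a fit of 4 grade means and cancel within each grade, so the simulated grade means hardly varied. These 0 false calls are thus largely set by the simulation, which cannot show the effect of noise shared by a slide or grade. In simulated data with independent tumours the false calls were 10 for the trend and 6 for Grade 4 minus Grade 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

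Alternatives fixed before the data were examined were high-level thresholds of 0.8, 1 and 1.5, values not centred again, tumours with a shared leading number in their titles averaged (same grade) or the second left out (different grades), each tumour left out, each probe's median subtracted, slide as a fixed or random block, eBayes with trend and robust, an F test and a fit of 2 grades. Alternatives added after seeing the data were high-level thresholds of 2.5 and 3, thresholds of 0.75 and 1.25 for the altered share, thresholds of the core median and the group levels, thresholds of 1.5 to 3 for the extent of the shared set, other numbers of components, centring on the mode, arrays scaled to one spread and array weights.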

Results

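Genomic DNA from 15 mammary carcinomas of a transgenic mouse line on the Balb/c background was compared with liver DNA of the same line by array comparative genomic hybridisation, in which tumour and reference DNA carrying different dyes compete for the same probes. The line carries simian virus 40 sequences under the promoter of whey acidic protein, a milk protein gene. The tumours were graded 1 to 4, with 3 tumours of Grade 1, 4 of Grade 2, 5 of Grade 3 and 3 of Grade 4. Each array gave a log2 ratio for 42076 probes, without missing values. The direction of the ratio was not recorded. Positive values were taken as likely tumour over liver, since values of up to 6.89 (a ratio of 119) occurred in these tumours while the lowest value of any array was -2.47. All amplifications, gains and losses named below rest on that direction. Array noise, as the SD estimated from the median absolute deviation over all probes, ran from 0.208 to 0.415 and also holds copy changes. The number of arrays limits the precision of every comparison. Grade and slide overlapped almost wholly: slide 1 held the 3 Grade 1 tumours and 1 of Grade 2, slide 2 held 3 of Grade 2 and 1 of Grade 3, slide 3 held 4 of Grade 3 and slide 4 the 3 of Grade 4. Nothing in the labels says that every tumour came from a different animal, and the p-values measure the spread between these tumours. The probes are identified here by array probe numbers alone, so the regions are described by the probes they hold, without gene names or positions.

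The first question was which tumours carried high-level amplification. A set of probes was amplified in 9 of the 15 tumours, and its core of 10 probes was at a log2 ratio of 2 or above in each of the 9. The median over the core ranged from 2.84 to 6.11 in these tumours, which corresponds to ratios from 7.16 to 69.1. In the other 6 tumours the core median lay between -0.18 and 0.25, and no core probe exceeded 0.48. The set was found in none of the 3 Grade 1 tumours, in 1 of the 4 Grade 2 tumours, in all 5 Grade 3 tumours and in all 3 Grade 4 tumours. Its presence rose with grade, with Spearman's rho 0.83 and Pearson's r 0.82 (exact permutation p = 0.000799 for each, two-sided, n = 15). The 3 Grade 1 tumours lie equally far from the median grade, farther than any other. The r was 0.76 without any 2 of them and 0.70 without all 3. Within slides the relation could not be settled. On slide 1 the set was absent from 3 Grade 1 tumours and present in the 1 of Grade 2. On slide 2 it was absent from 3 Grade 2 tumours and present in the 1 of Grade 3. The exact permutation p within slides was 0.0625, the smallest that the 16 arrangements allow. The level did not differ detectably between the 2 highest grades, with a mean core median of 5.24 ± 0.63 (SD, n = 5) in Grade 3 and 4.38 ± 1.64 (SD, n = 3) in Grade 4 (exact permutation p = 0.339, two-sided).

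**Figure D1:**
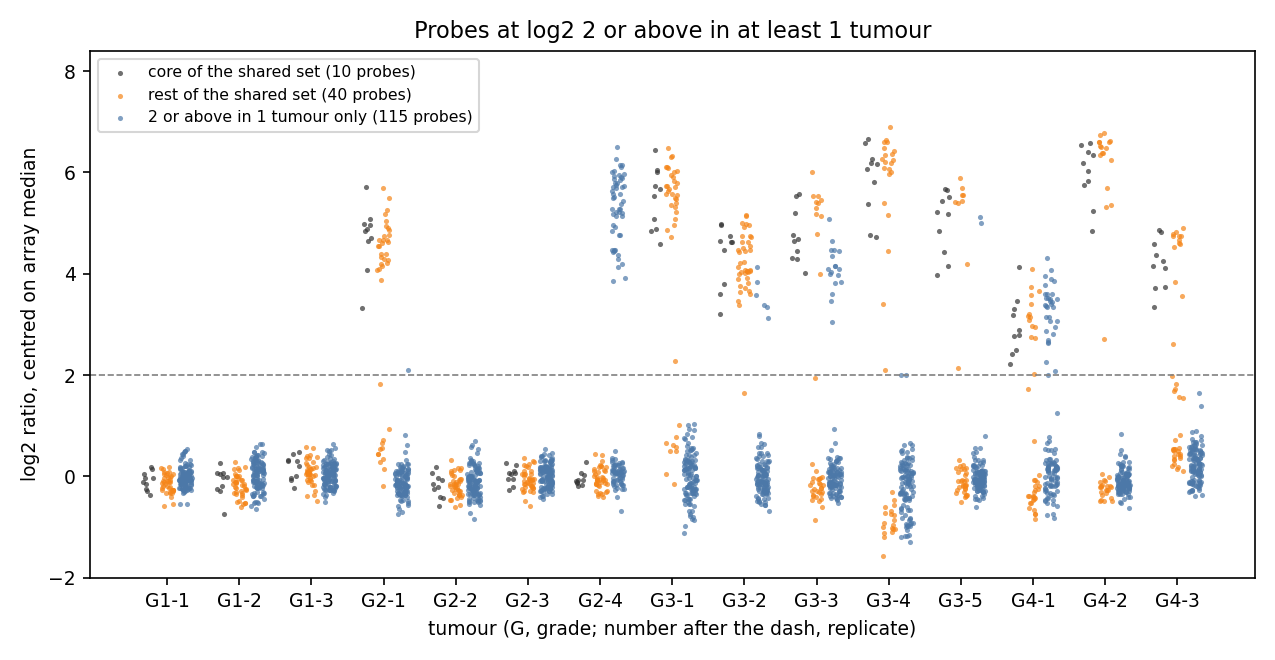
Log2 ratios (y axis, centred on each array's median) of the 165 probes at 2 or above (dashed line) in at least 1 tumour, for each of the 15 tumours (x axis); each point is 1 probe, with the 10 core probes in black, the other 40 shared probes in orange and the 115 probes at 2 or above in 1 tumour only in blue. The core lies above the line in 9 tumours, and the blue probes stand high mainly in Grade 2 replicate 4, Grade 4 replicate 1 and Grade 3 replicate 3.

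The amplified sets differed in extent between tumours. Altogether 165 probes reached 2 in at least 1 tumour, 50 of them in 2 or more tumours and 115 in a single tumour. The 50 shared probes fell into 11 combinations of tumours, against 38 to 49 when each tumour's probes were shuffled. The shuffling breaks up all joint amplification, so this shows only that probes were amplified together. Leaving out 2 probes, the remaining 48 could be placed in one linear order in which the probes amplified in any tumour were neighbours, with the core in the middle. The order was searched for in these same values, without positions and without shuffled sets for comparison. It therefore does not show that the probes lie together in the genome. The number of probes at 2 or above ran from 21 in Grade 3 replicate 5 to 57 in Grade 4 replicate 1. Grade 2 replicate 4 carried none of the shared probes and had 53 probes of its own, with a median of 5.44. Grade 4 replicate 1 had 33 probes of its own (median 3.38) and Grade 3 replicate 3 had 18 (median 4.09), besides the shared set. In the 10 tumours 12 values lay from 2 to 2.5 and 376 at 2.5 or above. A further 102 lay from 1.5 to 2, 63 of them in Grade 3 replicate 4 and 11 of them at the 165 probes. The size of the core depends on the threshold: it was 16 probes at 1.5, 8 at 2.5 and 4 at 3, while the shared probes numbered 53, 49 and 49 and their combinations of tumours 12, 11 and 14. No probe reached 2 in the 5 tumours without an amplified set, whose highest value was 1.49. Only 3 probe values, all in Grade 1 replicate 2, were at -2 or below.

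The second question was which larger parts of the genome were gained or lost. Because neighbouring probe numbers were unrelated (correlation of -0.0089 to 0.0085), the genome was described through groups of probes that shifted together over the 15 tumours. There were 14 such groups, of 659 to 1983 probes, holding 17078 probes (40.7% of the 41911 without high-level values). Group 6 (1300 probes) was gained by at least 0.25 in 9 tumours and lost in none, with the highest level, 0.59, in Grade 2 replicate 1 and a mean of 0.25 ± 0.19 (SD, n = 15). Group 10 (1053 probes) was gained in 7 tumours, with a mean of 0.23 ± 0.17 (SD, n = 15). Group 1 was above 0 at 0.13 ± 0.16 and group 12 at 0.13 ± 0.13, while group 9 was below 0 at -0.16 ± 0.24 and group 11 at -0.14 ± 0.15 (SD, n = 15). These 6 groups differed from 0 by an exact sign-flip permutation test. The groups were formed from these same values, so probes gathered for lying on one side of 0 on most arrays pass readily. The lowest level was 0.0025 in group 10 and 0.013 in group 12, so both were above 0 in all 15 tumours. The Benjamini-Hochberg adjusted p over 14 groups was 0.00171 for group 6, 0.000427 for groups 10 and 12, 0.0156 for group 1, 0.0338 for group 9 and 0.00641 for group 11. No dye swaps were made and all 105 pairs of arrays correlated positively (median r 0.456), so a small mean shared by most arrays, as in group 1, can hold a bias of its probes.

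**Figure D2:**
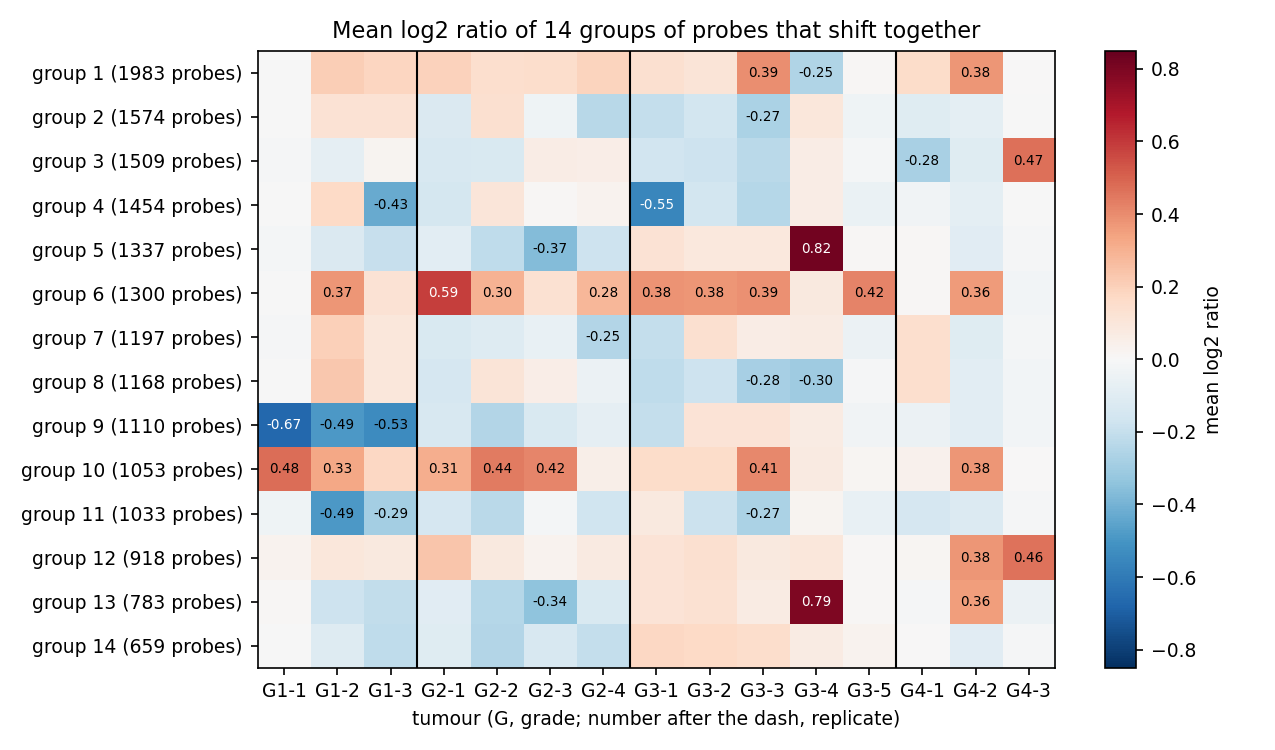
Mean log2 ratio of 14 groups of probes (rows, with their number of probes) in the 15 tumours (columns, ordered by grade, black lines between grades); colours run from blue (below 0) to red (above 0), and the number is printed where the level is at least 0.25 from 0. Group 6 is gained in 9 tumours and group 9 is lost in the 3 Grade 1 tumours.

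Some shifts were found in few tumours. In Grade 3 replicate 4, group 5 (1337 probes) stood at 0.82 and group 13 (783 probes) at 0.79, the largest levels of any group. Group 4 was lost in Grade 3 replicate 1 (-0.55) and Grade 1 replicate 3 (-0.43). Group 12 was gained in 2 of the 3 Grade 4 tumours, at 0.38 in replicate 2 and 0.46 in replicate 3, and reached 0.25 in no other tumour. Group 3 was gained in Grade 4 replicate 3 (0.47) and lost in Grade 4 replicate 1 (-0.28). Some of these levels depend on how the members were chosen. With members set from the other 14 tumours, group 3 in Grade 4 replicate 1 was at -0.18 and no longer past 0.25, and group 12 was at 0.47 in Grade 4 replicate 2 and 0.27 in Grade 4 replicate 3. Of the 14 groups, 2 (groups 6 and 10) were altered in the same direction in at least 4 tumours.

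The third question was whether copy number followed grade. Group 9 (1110 probes) was lost in all 3 Grade 1 tumours, at -0.67, -0.49 and -0.53, and in none of the other 12, whose levels ran from -0.246 to 0.12. With members set from the other 14 tumours the lowest of these, Grade 2 replicate 2, was at -0.251, just past the bound of 0.25. Its mean was -0.56 ± 0.09 (SD, n = 3) in Grade 1, -0.15 ± 0.07 (SD, n = 4) in Grade 2, 0.01 ± 0.14 (SD, n = 5) in Grade 3 and -0.06 ± 0.03 (SD, n = 3) in Grade 4. It was the only one of 14 groups whose level followed grade after adjustment (rho 0.72, permutation p = 0.0034, adjusted p = 0.0476; r 0.77, permutation p = 0.00062, adjusted p = 0.00868; n = 15). The relation rests on the Grade 1 tumours, since r was 0.62 to 0.64 without 2 of them and 0.36 without all 3. The count of groups rests on single tumours. It was 0 without any one of the Grade 1 or Grade 2 tumours, without Grade 3 replicate 5 or without Grade 4 replicate 3, and 3 without Grade 4 replicate 2. The rho of group 9 stayed between 0.66 and 0.79 with any one tumour left out. With slide as a fixed block the partial correlation was 0.53 (exact permutation p = 0.25, where 0.0625 is the best possible), so that test could not reach 0.05. On slide 1 the Grade 2 tumour was at -0.13, above the 3 Grade 1 tumours (exact permutation p = 0.25, the smallest for 3 against 1). On slide 2 the Grade 3 tumour was at -0.20 against a mean of -0.15 in 3 Grade 2 tumours (exact permutation p = 0.75). Grade 4 against Grade 1 gave an exact permutation p of 0.1, the smallest for 3 against 3.

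**Figure D3:**
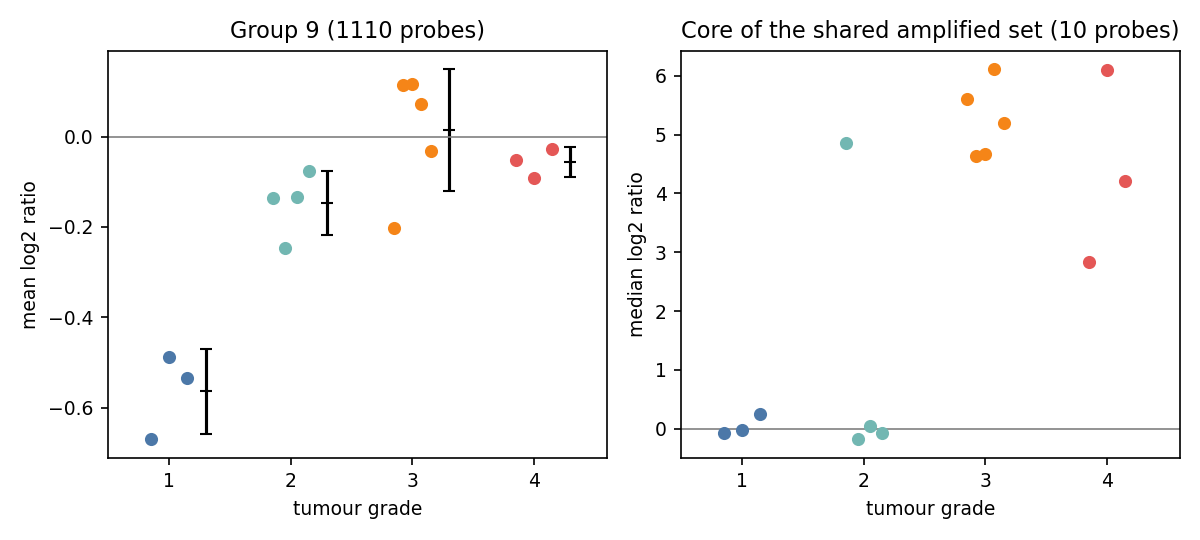
Level of group 9 (left, mean log2 ratio over 1110 probes) and of the core of the shared amplified set (right, median log2 ratio over 10 probes) in each tumour (points) by tumour grade (x axis); bars at left are the mean ± SD of the grade. Group 9 lies at -0.49 or below in the 3 Grade 1 tumours only, and the core lies at 2.84 or above in 9 tumours, 8 of them of Grade 3 or 4.

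Of single probes, 741 of 42076 followed grade (limma, Benjamini-Hochberg adjusted p under 0.05), 570 rising and 171 falling. Most of the rising probes belonged to the block lost in Grade 1: 341 of them, 59.8%, lay in group 9, which holds 2.64% of all probes. A further 23 were among the 50 shared amplified probes, 24 lay in group 12, and 114 lay in no group. Of the falling probes, 32 lay in group 2, 12 in group 8, 10 in group 10 and 108 in no group. The smallest p for a rise was at A_53_P156878, with a mean log2 ratio of -0.91 ± 0.01 (SD, n = 3) in Grade 1 and 0.09 ± 0.10 (SD, n = 3) in Grade 4 (slope 0.35 ± 0.05 per grade, SE, limma adjusted p = 0.0159). The next was A_53_P179905, with means of -0.72 and 0.41 (slope 0.39 ± 0.06, limma adjusted p = 0.0159). A_53_P138347 fell from a mean of 0.34 in Grade 1 to -0.46 in Grade 4 (slope -0.29 ± 0.05, limma adjusted p = 0.0159) and A_53_P129956 from 0.48 to -0.32 (slope -0.27 ± 0.05, limma adjusted p = 0.0176). With slide as a fixed block 24 probes rose and 5 fell. Slides 3 and 4 each hold 1 grade, so this slope rests on slides 1 and 2 alone. There it sets Grade 2 replicate 1 and Grade 3 replicate 1 each against 3 tumours of its slide. Without Grade 1 replicate 1 or without Grade 1 replicate 3 none passed, while 7901 and 6695 had an unadjusted p under 0.05, against 7718 with all tumours. The count was 21 without Grade 1 replicate 2, 372 and 392 without replicates 2 and 3 of Grade 2, 378 without Grade 3 replicate 5, 265 and 324 without replicates 1 and 2 of Grade 4, and 2020 without Grade 3 replicate 1, the noisiest array.

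Between the ends of the grading scale, 355 probes were higher and 31 lower in Grade 4 than in Grade 1 (limma, adjusted p under 0.05, 6467 at an unadjusted p under 0.05). Of the 355, 272 (76.6%) lay in group 9 and 10 among the shared amplified probes. The 2 comparisons called 349 probes in common with the same sign. This count rests on single tumours too, and was 0 with tumours of a shared title number averaged or the second left out. It was 0 without Grade 1 replicate 1, Grade 1 replicate 2 or any one Grade 4 tumour, 78 without Grade 1 replicate 3, 937 without Grade 3 replicate 1, 746 without Grade 3 replicate 4 and 214 without Grade 2 replicate 3. A fit with slide as a fixed block cannot be had, since slide 4 holds the Grade 4 tumours alone, and with slide as a random block 347 rose and 28 fell.

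No relation of the altered share of the genome to grade was detected in these 15 tumours. The cut of 1 for single probes lies above the largest group level, 0.82, so it counts few of the probes in shifted groups. By this cut Grade 3 replicate 3 had 0.269% of probes altered, against 47.0% by weight in altered components of the mixture. Probes at least 1 from 0 made up 0.320% ± 0.236 (SD, n = 3) of the array in Grade 1, 0.313% ± 0.286 (SD, n = 4) in Grade 2, 1.08% ± 1.00 (SD, n = 5) in Grade 3 and 0.324% ± 0.170 (SD, n = 3) in Grade 4. Spearman's rho with grade was 0.20 (permutation p = 0.48) and Pearson's r 0.18 (permutation p = 0.54, n = 15). The r was 0.06 to 0.16 without 2 of the 3 Grade 1 tumours and 0.06 without all 3. Grade 4 did not differ from Grade 1 (exact permutation p = 1, with 0.1 the smallest possible). This share rose with the noise of the array (rho 0.80, permutation p = 0.00061, adjusted p over 6 relations 0.00366). The r was 0.73 (permutation p = 0.0003, adjusted p 0.0018), and 0.67 without the 2 arrays whose noise lay farthest from the median. Both quantities measure the spread of the same values, so such a relation is partly built in and does not show technical noise as the cause. The noise itself did not follow grade (rho -0.01, permutation p = 0.964; r 0.03, permutation p = 0.928). The share of probes that belong to an altered one of the 14 groups ran from 3.10% in Grade 3 replicates 2 and 5 to 19.4% in Grade 3 replicate 3 and did not follow grade either (rho -0.04, permutation p = 0.890; r 0.07, permutation p = 0.798). Nor did the share by weight of all components of the mixture, stable or not, with a mean at least 0.25 from 0, which ran from 3.92% in Grade 2 replicate 4 to 47.0% in Grade 3 replicate 3 (rho -0.02, permutation p = 0.939; r 0.05, permutation p = 0.872). The number of probes at 2 or above gave a rho with grade of 0.59 (permutation p = 0.0241), and an r of 0.61 (permutation p = 0.0173). Neither passed the adjustment over 6 relations (adjusted p = 0.0722 and 0.0518), and r was 0.46 without any 2 of the Grade 1 tumours and 0.28 without all 3. Within slides, the tumour of the higher grade had the highest share of probes at least 1 from 0 on slide 1 (0.708% against a mean of 0.320%) and on slide 2 (1.66% against 0.181%), each with an exact permutation p of 0.25, the smallest for 3 against 1.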

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

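The tests of explanations in this part were chosen after the results were seen, except the fit with slide as a fixed block for single probes, which had been fixed before. Among 40 sets of 4 or 5 tumours of one grade that were examined for a tumour far from the rest, 5 stood out, against 2 expected by chance at 1 in 20. In Grade 2 the core of the shared amplified set had a median of 4.86 in replicate 1, with the next tumour at 0.05. In Grade 3, replicate 3 had 47.0% of probes, by weight, in altered components of the mixture, stable or not, with the next at 17.9%; its 19.4% in altered stable groups did not stand out in this way. Grade 3 replicate 4 stood apart in 3 groups: group 5 at 0.82 (next 0.12), group 13 at 0.79 (next 0.13) and group 6 at 0.081, below the next at 0.38.

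The shared amplified set was found in 9 tumours, 8 of them of Grade 3 or 4. An uneven spread over grades by chance is argued against by the exact permutation test (p = 0.000799). The test takes the tumours as independent, and the set and its threshold of 2 were chosen after seeing the data, so chance is not excluded. A low share of tumour cells in the Grade 1 samples could not be settled. Probes in altered groups made up a mean of 8.16% in Grade 1, against 7.93% in Grade 4. This does not measure the share of tumour cells, and in Grade 1 it includes group 9, whose loss slide leaves open. Some shifts differed between the Grade 1 tumours, all on slide 1. Group 10 was at 0.48 in replicate 1, group 11 at -0.49 in replicate 2 and group 4 at -0.43 in replicate 3. These shifts argue against samples almost free of tumour cells, but do not give the share. The highest core median in Grade 1 was 0.25, under the 1.47 that the weakest amplification seen would give in cells with both copies of group 9 lost. This bound takes that loss as settled, which slide leaves open, and assumes the level of the amplification. An amplification in a small part of the tumour cells stays open. Slide as the whole cause is argued against on slides 1 and 2, where 1 tumour of 4 had the set and the other 3 did not. The core median of the tumour with it exceeded the highest of the 3 without it by 4.61 on slide 1 and 5.55 on slide 2. The range over the 6 tumours without the set was 0.43. The core was chosen for being at 2 or above in every tumour with the set, so the size of these gaps is built in and adds no evidence. On slides 3 and 4 all 7 tumours had it and slide cannot be told apart from grade, and the 16 arrangements within slides give at best an exact permutation p of 0.0625. A relation of the amplification to tumour progression stays open as a biological explanation.

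The 741 probes that followed grade exceeded what all but 1 of 99 other assignments of the grades gave (2 of 100 with the real one included, highest other 1475). Such a count was thus rare by chance, but chance was not excluded. The grades were shuffled across slides, so these assignments do not keep the overlap of grade and slide. The assignment with 1475 probes ran partly against grade (Spearman's rho -0.53 with grade and -0.56 with slide); what sets it apart was not tested. One block of probes lost in Grade 1 may account for most of the rise, since 59.8% of the rising probes lay in group 9. With slide as a fixed block, where the slope rests on slides 1 and 2 alone, 29 probes passed, 18 of them among the 741 with the same sign. The median slope went from 0.23 to 0.17 for the 570 rising probes and from -0.21 to -0.14 for the 171 falling ones. Of the called probes 86.6% kept their sign, against 53.9% of all probes. The called probes were chosen for large slopes in these same values, part of which the blocked fit reuses. A higher share is thus built in and does not tell slide from grade. The median standard error of the called probes rose from 0.05 to 0.15. The call thus ended with smaller slopes and less precision, and slide cannot be told apart from grade. For Grade 4 against Grade 1, the 10 splits of the 6 tumours cannot give a share under 0.05; 1 of the 10, the real one, gave 386 probes and the highest other gave 0.

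The loss of group 9 was seen in the 3 Grade 1 tumours. A bias of its probes equal on every array is argued against: with members set from the other 14 tumours, the lowest of the other 12 tumours (-0.251) stood 0.245 above the highest of Grade 1 (-0.496), against an SD of 0.117 among the 12. The mixture itself had been fitted to all tumours. Slide stays open: the 1 Grade 2 tumour on slide 1 was at -0.13, above the Grade 1 tumours (-0.49 at most), but 1 tumour settles nothing. A loss in Grade 1 tumours themselves stays open as a biological explanation and was not tested further.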

How the results depend on the processing

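Results on probe groups, the shared set, its core and array weighting were added after the data were seen. No paired analysis was possible because replicate numbers were given in the order of the records and pair nothing. Segment penalties, segment thresholds and probes per gene were not run, since no positions were used; slide as a fixed block was not run for Grade 4 against Grade 1, which it leaves without an estimate. The shared set's relation to grade had rho 0.84 (exact permutation p = 0.00233) without the second tumour of each title number and 0.81 to 0.89 with a tumour left out; the other 4 alternatives changed no tumour's status and say nothing on stability, and within slides the exact permutation p was 0.0625. Tumours with high-level probes stayed at 10 at thresholds of 1.5 to 3 and were 15 at 0.8 and 1. The altered share against grade reached no p under 0.05 (rho 0.08 to 0.38 with a tumour left out). Its rho of 0.20 became 0.48 (permutation p = 0.0701) at the higher added threshold, 0.022 at the lower, -0.039 with altered groups and -0.022 with altered components of the mixture, stable or not. The 10 core probes became 16 at a threshold of 1.5 and 4 at 3.

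The 741 probes following grade became 333 with title numbers averaged or left out, 29 with slide as a fixed block, 366 in the F test, 2502 with arrays scaled to one spread and 4818 with array weights (0 to 2020 with a tumour left out). Scaling moved the split from 570 rising and 171 falling to 1648 and 854, and weights to 2892 and 1926. The 386 probes between Grade 4 and Grade 1 became 0 with title numbers, where 4666 had an unadjusted p under 0.05, 969 with these 2 grades only and 1663 with scaling (0 to 937 with a tumour left out). Here scaling moved the split from 355 higher and 31 lower to 1251 and 412. Fewer tumours enter the title setting; the other causes were not tested. Groups away from 0 numbered 4 to 7 throughout. Groups following grade numbered 2 with title numbers (0 to 3 with a tumour left out). Group 9 gave 0.53 with slide as a block (exact permutation p = 0.25, with 0.0625 the best possible), against permutation p from 0.00126 to 0.0123 with a tumour left out. The 2 groups altered in at least 4 tumours became 11 at a threshold of 0.15, 1 at 0.4 and 4 with at least 3 tumours. Signal over background was not used here.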

Other observations

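The tests in this part were chosen after the values were seen. Probes of the shared set that were below 2 in a carrier tumour often stood away from 0. Some of them were clearly raised, with a highest value of 1.98 in Grade 4 replicate 3 and 1.95 in Grade 3 replicate 3. In 5 of 8 tumours their median lay outside the range of medians of random sets of as many probes. The random sets were drawn from all probes, and probes that shift together leave such a range more readily. In Grade 3 replicate 4 the 19 such probes had a median of -0.92, while medians of random sets of 19 probes ran from -0.41 to 0.35. In Grade 4 replicate 1 the 26 such probes were at -0.39 (random sets from -0.28 to 0.29), both below. Above lay Grade 4 replicate 3 with 27 such probes at 0.50 (random sets from -0.15 to 0.19), Grade 2 replicate 1 with 12 at 0.50 (-0.335 to 0.39) and Grade 3 replicate 1 with 9 at 0.59 (-0.62 to 0.54). The median was thus lower in 2 tumours and higher in 3. The probes amplified only in Grade 3 replicate 3 and those amplified only in Grade 4 replicate 1 were both assigned, from the other 14 tumours, to 1 component of 325 probes, which was not among the stable groups and stood at 0.51 in Grade 4 replicate 3. Of the former 88.9% fitted best there on their own, and of the latter 42.4%. The best fit was not close for the former in every tumour. Their median was -0.735 in Grade 3 replicate 4 and -0.35 in Grade 4 replicate 1, where the component stood at -0.139 and 0.039. Probes of the shared set below 2 had medians of -0.92 and -0.39 in these tumours, which lie nearer. This likeness was not tested. The 53 probes of Grade 2 replicate 4 were assigned to group 7, where 83.0% of them fitted best on their own.

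Grade 1 replicate 1, the array with the least noise, had 1 group lost (group 9, -0.67), 1 gained (group 10, 0.48) and the other 12 within 0.04 of 0. A hypothesis is a loss and a gain of 1 copy in the same share of the DNA. The loss would then put that share at 74.3% and the gain at 0.46, and the measured gain differed from this by 0.0215, within the 0.05 set as the bound. With the sign turned, as for a ratio of liver over tumour, the predicted and measured gains differed by 0.312, and the measured 0.67 would exceed the 0.58 of a 1-copy gain in all cells. A gain of 2 copies could reach it, so these levels leave the direction open.

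The titles of 2 pairs of tumours share a leading number, and a shared origin may be behind it. Over the 14 group levels, each centred over tumours, the pair in Grade 2 had r = 0.38 and the pair of Grade 3 and Grade 4 had r = 0.34, against a median of -0.07 over all 105 pairs. A mean as high was found in 152 of 4095 ways to choose 2 pairs (exact p = 0.0371, one-sided). The latter pair had 3 of 8 altered groups in common and the former 0 of 5. The former also shared a grade and a slide. Its r lay between those of its members with Grade 2 replicate 2 of the same slide (0.69 and 0.21). The exact p is set against pairs of any grade and slide, so it does not isolate a shared origin and the question stays open.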
